A study of Mus musculus with 4 samples.

How the data were processed

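Thymic CD3+ CD1d-PBS57+ cells of BALB/c and B6 mice (2 libraries each) were sorted, and their TCR transcripts were amplified with a droplet-based 5' single-cell kit. The authors assembled the contigs with Cell Ranger 7.1.0 and name the genome build GRCm38; the release of the V(D)J reference is not stated in the sources used here. The deposited files list, for each contig of each cell barcode, the segments, the CDR sequences and a count of UMIs and a count of reads, with no normalization. Contig length, the deposited value of the other unit, was not used. All listed contigs were marked as from a cell, high confidence, full length and productive.

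Invariant cells were barcodes with a productive TRAV11 or TRAV11D chain joined to TRAJ18. Strain comparisons used the 10635 of these with exactly 1 productive TRB chain, 1162 in BALB/c 1, 896 in BALB/c 2, 1689 in B6 1 and 6888 in B6 2. No doublet caller was run. Contigs deposited under a joint name of TRBV12-2 and TRBV13-2 (6535 contigs) were assigned by their CDR1 and CDR2 sequences, and 3 that matched no segment exactly were counted as TRBV13-2. In all, 6534 were counted as TRBV13-2 and 1 as TRBV13-1. In invariant cells the limit that a count of 0 allows, 3 counts, was 0.258%, 0.335%, 0.178% and 0.0436% in these libraries. The positions of 38 of 38 segments were taken from the GRCm38.p6 annotation of C57BL/6J, where TRBV10 and TRBV29 are annotated as V segment pseudogenes.

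Cells per TRBV or TRBJ segment, and residues of the CDR3 beta without the first 4 and last 4, were summed per library and tested with the edgeR 4.0.16 quasi-likelihood F test. The library size was all cells of the library, without TMM factors or an abundance trend. Segments with under 10 cells over the 4 libraries were not tested but stayed in the totals. P values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Invariant and other cells of the same library were compared with library as a block. TRBV lists were tested with fry from limma 3.58.1, which asks whether the members move in a common direction. Single values per library were compared with an exact two-sided permutation test over the 6 arrangements of 2 against 2 libraries, whose smallest p is 0.333. Repeated clonotypes were counted after thinning every library to 896 cells, as the mean of 100 seeded draws. Shares in single libraries have 95% Wilson intervals.

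The populations, tests, lists, alternatives from the plan and the rule for named segments were fixed before the data were examined. That rule took every TRBV and TRBJ segment past the threshold, all members of the TRBV lists, and the 5 TRBV and 3 TRBJ with the largest absolute log2 fold change. It also took the 5 TRBV and 3 TRBJ with the most cells, up to 6 amino acids past the threshold, and the 3 most frequent clonotypes and CDR3 alpha sequences. The lists were Vβ8 (TRBV13-1, TRBV13-2, TRBV13-3), Vβ7 (TRBV29), Vβ2 (TRBV1), the superantigen list (TRBV26, TRBV12-1, TRBV12-2, TRBV16, TRBV15) and the Mls-1 list (TRBV19, TRBV13-3, TRBV17). TRBV13-3 is in both the Vβ8 and the Mls-1 list.

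Alternatives covered each library left out, replicate number as a block, TMM factors, each clonotype counted once and the TRB chain with most UMIs in cells with several. They also covered a minimum of 3 UMIs, all cells with 1 TRB, other filters on low counts, TRBV13-2 cells alone, DESeq2 1.42.0, limma on log2 odds with 0.5 added and edgeR's abundance trend. Other work used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

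The edgeR test was tested on 200 simulated tables per setting, each with 2 changed items. For changes of 1.5-fold, 2-fold and 4-fold it recovered 14.3%, 38.0% and 72.8% of changed TRBV segments, 35.5%, 83.5% and 98.5% of TRBJ segments and 75.0%, 91.0% and 96.3% of residues. Between 0.389% and 1.44% of unchanged items were called. Changed items were drawn from those with a share of at most 0.25, so TRBV13-2 was never changed. All items and libraries of a table had 1 dispersion, so these rates do not cover a spread that differs between the strains.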

Results

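Paired T cell receptor (TCR) sequences were collected from single thymic cells of BALB/c and B6 mice, sorted as CD3+ cells that bind the CD1d-PBS57 tetramer, the reagent that marks invariant natural killer T (iNKT) cells. The data comprised 2 libraries per strain. BALB/c 1 held 1760 cell barcodes with 43753 TCR UMIs, and BALB/c 2 held 1455 barcodes with 38171 UMIs. B6 1 held 2315 barcodes with 53823 UMIs, and B6 2 held 8660 barcodes with 227381 UMIs. Reads per UMI were 612, 715, 574 and 197 in the same order. The labels do not say whether the libraries of a strain came from separate animals, so every spread given is a spread between libraries. Differences are BALB/c minus B6, and positive log2 fold changes are higher in BALB/c. A mean with its SD is over n = 2 libraries per strain unless stated. Intervals for single libraries are 95% Wilson intervals and cover counting error only.

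Most sorted cells carried the invariant alpha chain, the rearrangement of TRAV11 to TRAJ18 that defines iNKT cells. Among cells with both a TRA and a TRB chain, it was found in 88.3% of BALB/c 1 (interval 86.5 to 89.8), 83.9% of BALB/c 2 (81.7 to 85.9), 92.4% of B6 1 (91.1 to 93.4) and 95.8% of B6 2 (95.4 to 96.3). The mean share was 86.1% ± 3.08 in BALB/c and 94.1% ± 2.46 in B6. The difference of -8.00 percentage points separated all libraries of the strains, with an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow. Cells in which only other TRA chains outside the named classes were found made up 10.1% and 12.9% of BALB/c barcodes and 6.39% and 3.76% of B6 barcodes. The other named classes were rare. Chains of mucosal-associated invariant T (MAIT) cells, TRAV1 with TRAJ33, were found in 0 of the 1760, 1455, 2315 and 8660 barcodes, and chains of TRAV10 with TRAJ50 in 0, 0, 1 and 1. That class was meant to hold Vα10 NKT cells, but whether TRAV10 is the segment of that name was not established, so the count does not bear on their frequency. TRAV13 with TRAJ50, chosen after its values were seen, was found in 11, 8, 1 and 2 cells. TRAJ18 joined to another TRAV was named in 8, 7, 7 and 12 barcodes. Of all 40 such chains, 13 had the framework 1 sequence of TRAV11, and these were among the 19 named TRAV6. No TRA was found in 16.7% and 19.1% of BALB/c barcodes and in 12.2% and 6.44% of B6 barcodes.

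The invariant chains of the strains carried different CDR2 sequences. The CDR2 alpha was LVHENDK in 1280 of 1280 invariant chains of BALB/c 1 and 982 of 983 of BALB/c 2. It was LVDQKDK in 1876 of 1876 chains of B6 1 and 7769 of 7769 of B6 2. Neither form was found in the other strain, where a count of 0 allows up to 0.234%, 0.305%, 0.160% and 0.0386% of chains in the order BALB/c 1, BALB/c 2, B6 1 and B6 2. The CDR3 alpha, by contrast, was nearly uniform. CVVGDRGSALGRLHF made up 92.1% ± 2.78 of the chains in BALB/c and 94.3% ± 0.31 in B6. The difference of -2.20 points was smaller than the spread between the BALB/c libraries (exact permutation p = 0.333). Without BALB/c 1 the difference was -4.17 points and without BALB/c 2 it was -0.237 points. With each nucleotide sequence counted once per library, it turned to 6.68 points (exact permutation p = 0.667). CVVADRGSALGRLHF made up 3.36% and 4.17% of chains in BALB/c 1 and 2 and 2.67% and 2.47% in B6 1 and 2. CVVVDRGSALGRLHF made up 1.88%, 3.66%, 2.19% and 2.07%. TRAV11 lies on chromosome 14 from 53519303 to 53519859 and TRAJ18 from 54200777 to 54200842 in GRCm38.

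More than a single productive chain per cell was found at low shares. Another productive TRA was present in 4.19% ± 0.0338 of invariant cells in BALB/c and 4.84% ± 0.32 in B6, a difference of -0.643 points (exact permutation p = 0.333). In BALB/c 1, 9 of the 54 such cells belonged to 1 clonotype of TRBV29 with TRBJ1-2. No version of this share with each clonotype counted once was run. The median invariant cell had 5, 5, 6 and 7 TRA UMIs in BALB/c 1, BALB/c 2, B6 1 and B6 2. Without B6 1 the difference was -0.417 points, and with at least 3 UMIs per contig it was -0.228 points (exact permutation p = 0.667). In cells with at least 10 TRA UMIs it turned to 7.07 points, with shares of 20.1% ± 1.62 in BALB/c and 13.1% ± 3.11 in B6. That filter favours cells with another TRA, since the added chain counts towards their TRA UMIs. Another productive TRB was present in 6.82% ± 0.211 and 8.65% ± 1.84 of invariant cells, a difference of -1.83 points (exact permutation p = 0.333) that includes any doublets. Without B6 1 that difference was -3.13 points, and without B6 2 it was -0.534 points.

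Within each library, cells with the invariant chain used a narrow set of TRBV segments, set against 785 sorted cells in which only other TRA chains were found. Of 19 TRBV segments tested, 18 differed between these classes, 4 higher and 14 lower in invariant cells (edgeR, adjusted p under 0.05). TRBV13-2, which encodes Vβ8.2, was 3.18-fold higher in invariant cells (log2 1.67, SE 0.13, adjusted p = 1.89e-17). TRBV29, which encodes Vβ7, was 2.29-fold higher (log2 1.20, SE 0.20, adjusted p = 1.40e-07). TRBV13-1 (Vβ8.3) was 1.65-fold higher (log2 0.72, adjusted p = 0.00055) and TRBV1 (Vβ2) 1.59-fold higher (log2 0.67, adjusted p = 0.00201). The lower segments included TRBV31 (log2 -1.92), TRBV10 (-2.63), TRBV5 (-3.18), TRBV19 (-3.35), TRBV15 (-4.64) and TRBV17 (-1.45). TRBV20 and TRBV14 were found in 0 of 10635 invariant cells against 23 and 13 of 785 other cells. With 3 counts over all libraries set in place of 0, their shares were 104-fold and 58.7-fold lower. Those folds take the counts of other cells as exact, so they are not lower bounds. They and the ratios that follow pool the cells of all 4 libraries, of which B6 2 gave 6888 of 10635 invariant cells and 312 of 785 other cells. TRBV2 was found in 2 invariant cells and was 305-fold more frequent in other cells (exact interval 79.6 to 2594). TRBV12-1, TRBV16 and TRBV12-2, with 3 invariant cells each, were 181-fold (57.5 to 913), 140-fold (43.7 to 716) and 108-fold (32.9 to 562) more frequent there. TRBV26 counted 4 invariant cells against 19 other cells, and TRBV3 counted 1 against 44. TRBV13-3 (Vβ8.1) had a log2 fold change of 0.04 (adjusted p = 0.855).

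These class differences are relative to the plain cell totals. TMM scaling raised the median of all segments by 0.53 and DESeq2's size factors by 0.39 on the log2 scale. With TMM, TRBV13-3 was called higher (log2 0.62, adjusted p = 0.0118) and TRBV17 was no longer called, nor was TRBV17 with DESeq2 or with at least 3 UMIs per contig. Without BALB/c 2 neither TRBV1 (log2 0.47, adjusted p = 0.107) nor TRBV17 (log2 -1.20, adjusted p = 0.0509) was called. The class difference was also tested for a dependence on strain. edgeR called 0 of 19 segments, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.784, and no other tool was run on that term. TRBV14 and TRBV20, with 0 invariant cells, could not have been called. For the others the SE ran from 0.37 (TRBV13-2) to 2.10 (TRBV3) on the log2 scale, so a sizeable dependence on strain could be missed.

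Between the strains, the TRBV usage of invariant cells was close. The question was whether BALB/c and B6 iNKT cells draw on different V beta segments. Vβ8, Vβ7 and Vβ2, the families typical of mouse iNKT cells, covered 96.3% ± 0.188 of the cells in BALB/c and 96.2% ± 0.0726 in B6. TRBV13-2 was the most used segment, with 51.4% ± 5.79 in BALB/c and 51.2% ± 1.17 in B6. TRBV29 followed with 13.0% ± 0.776 and 16.6% ± 0.0612, TRBV13-1 with 13.0% ± 0.435 and 12.3% ± 0.489, TRBV1 with 12.7% ± 5.49 and 9.74% ± 0.62, and TRBV13-3 with 6.10% ± 1.32 and 6.41% ± 0.0669. edgeR called 0 of 11 segments, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.397. DESeq2 and limma on log2 odds also called 0, each with 1 segment at an unadjusted p under 0.05. TRBV29 was lower in both BALB/c libraries than in both B6 libraries (log2 -0.34, SE 0.21, adjusted p = 0.397). The largest log2 fold changes were those of TRBV15 (1.75, SE 1.04), TRBV10 (-1.18, SE 0.67), TRBV5 (-0.83, SE 0.56), TRBV17 (0.80, SE 0.54) and TRBV1 (0.38, SE 0.31), none past the threshold. Of these, TRBV15 rests on 11 cells. Without BALB/c 1, TRBV5 was at -0.09 and TRBV17 at 0.15. Without BALB/c 2 they were at -2.04 and 1.26, and without B6 2 TRBV17 was at 0.24. Without BALB/c 1, TRBV1 was called higher in BALB/c (log2 0.81, adjusted p = 0.00599). In BALB/c 2, 83 of the 149 TRBV1 cells belonged to 1 clonotype. The TRBV1 fold change turned to log2 -0.10 without BALB/c 2 and to -0.08 with each clonotype counted once.

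**Figure D1:**
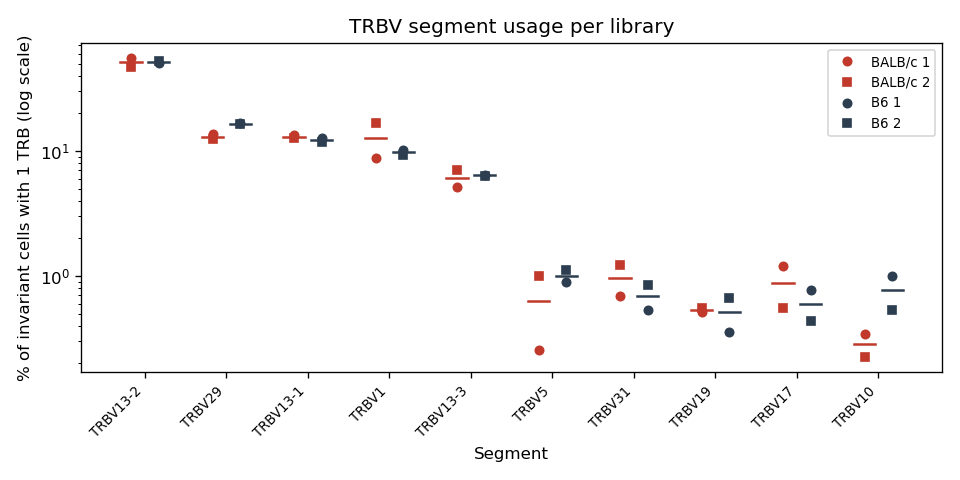
Share of invariant cells (%, log axis) that use each of 10 TRBV segments, with 1 point per library and a bar at the mean of each strain (n = 2 libraries). TRBV13-2 lies between 47.3% and 55.5% in all 4 libraries, and the points of TRBV29 are lower in BALB/c (12.5% and 13.6%) than in B6 (16.6% in both), a difference that did not pass the test.

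No V beta list fixed in advance passed the threshold when all cells were counted. The Vβ8 list (TRBV13-1, TRBV13-2 and TRBV13-3) covered 70.5% ± 4.90 of invariant cells in BALB/c and 69.9% ± 0.609 in B6, a difference of 0.663 points (exact permutation p = 1.0). That sign was not stable, since without BALB/c 1 the difference was -2.80 points and without BALB/c 2 it was 4.13 points. By fry, the Vβ8 list had an adjusted p of 0.366. The Mls-1 list (TRBV13-3, TRBV17 and TRBV19), segments whose T cells are deleted by a viral superantigen that neither strain is known to carry, covered 7.52% ± 0.893 and 7.52% ± 0.0822. Its fry p was 0.0299 (adjusted p = 0.0597) towards higher in BALB/c, although its median log2 fold change was -0.08 and its mean 0.20. The superantigen list, segments reported to be deleted in strains with I-E and endogenous superantigens, covered 0.314% ± 0.286 and 0.190% ± 0.0181. Only 1 of its 5 members, TRBV15, had enough cells for a test, so it has no set test. TRBV26, TRBV12-1, TRBV12-2 and TRBV16 had 4, 3, 3 and 3 cells. No member of any list passed the threshold over all segments or when adjusted over the list alone (0 members in edgeR). With each clonotype counted once, both tested lists passed by fry towards higher in BALB/c, with adjusted p values of 0.0436 for Vβ8 and 0.0294 for Mls-1. The Mls-1 list had been fixed as a negative control, so its passing weakens both calls. TRBV13-2, the largest Vβ8 member, then had mean shares of 50.3% in BALB/c and 50.8% in B6. TRBV13-1 (15.3% and 12.4%) and TRBV13-3 (7.05% and 6.34%), the member in both lists, had higher means in BALB/c. The shares were then 72.6% ± 0.224 and 69.6% ± 0.0104 for Vβ8, a difference of 3.02 points (exact permutation p = 0.333), and 8.68% ± 0.615 and 7.49% ± 0.0604 for Mls-1.

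TRBJ usage differed between the strains, with TRBJ1 segments higher and TRBJ2 segments lower in BALB/c among those called. edgeR called 5 of 12 TRBJ segments, each with an adjusted p of 0.0260 and each on the same side in both libraries of a strain. TRBJ1-5 was 1.56-fold higher in BALB/c, with 8.44% ± 1.21 of cells against 5.46% ± 0.147 (log2 0.64, SE 0.14). TRBJ1-3 was 1.40-fold higher, with 7.99% ± 0.257 against 5.73% ± 0.192 (log2 0.49, SE 0.11). TRBJ2-2 was 1.67-fold lower, with 2.04% ± 0.0399 against 3.38% ± 0.171 (log2 -0.74, SE 0.15). TRBJ2-1 was 1.65-fold lower, with 7.25% ± 1.12 against 11.9% ± 0.0757 (log2 -0.73, SE 0.14). TRBJ2-7 was 1.38-fold lower, with 14.9% ± 0.0475 against 20.6% ± 0.448 (log2 -0.47, SE 0.096). In GRCm38 these J segments lie on chromosome 6, the TRBJ1 cluster from 41533864 (TRBJ1-1) to 41535606 (TRBJ1-6) and the TRBJ2 cluster from 41542754 (TRBJ2-1) to 41543856 (TRBJ2-7).

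The other TRBJ segments did not pass the threshold, and TRBJ1-1 had a negative log2 fold change of -0.39 (adjusted p = 0.273). TRBJ1-6 had the largest log2 fold change, 1.33 (SE 0.45, adjusted p = 0.0686), with 2.84% and 1.12% of cells in BALB/c 1 and 2 and 0.71% and 0.857% in B6 1 and 2. In BALB/c 1, 20 of its 33 cells belonged to 1 clonotype. With each clonotype counted once its shares were 1.28% and 1.26% against 0.663% and 0.912% (log2 0.56, adjusted p = 0.185), and without BALB/c 1 its log2 fold change was 0.43 (adjusted p = 0.430). TRBJ2-5 covered 17.2% ± 6.30 in BALB/c and 10.9% ± 0.0269 in B6 (adjusted p = 0.0918), and the 83-cell clonotype of BALB/c 2 uses it. TRBJ1-2 covered 13.0% ± 2.30 and 9.83% ± 0.912 (adjusted p = 0.0856). The TRBJ1 cluster as a whole was used by 52.8% of cells in BALB/c 1 and 39.7% in BALB/c 2, against 38.4% in B6 1 and 37.5% in B6 2. Without B6 1 and without B6 2 edgeR called 0 segments, each time with 1 at an unadjusted p under 0.05, where the spread within a strain comes from the BALB/c libraries alone. The fold changes of the 5 stayed close, for example log2 0.52 and 0.45 for TRBJ1-3 and -0.73 and -0.71 for TRBJ2-1, with adjusted p values of 0.146 and 0.256. Without BALB/c 2 the count was 9, the 5 and TRBJ1-2, TRBJ1-4 and TRBJ1-6 (higher) and TRBJ2-4 (lower). Without BALB/c 1 it was 7, the 5 and a pair that runs against the division by cluster, TRBJ1-1 lower (log2 -0.96, adjusted p = 0.0163) and TRBJ2-5 higher (log2 0.99, adjusted p = 0.00151). In all cells with 1 TRB, TRBJ2-2 was at log2 -0.34 and not called, with adjusted p = 0.194, the highest over its alternatives with all 4 libraries (lowest 0.0129). With all 4 libraries DESeq2 called 4 segments, 3 of them among the 5, and limma on log2 odds called 5, the same 5. A block of replicate number in edgeR kept 3 of the 5. Crossing those numbers, an alternative chosen after the data were seen, kept 0.

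**Figure D2:**
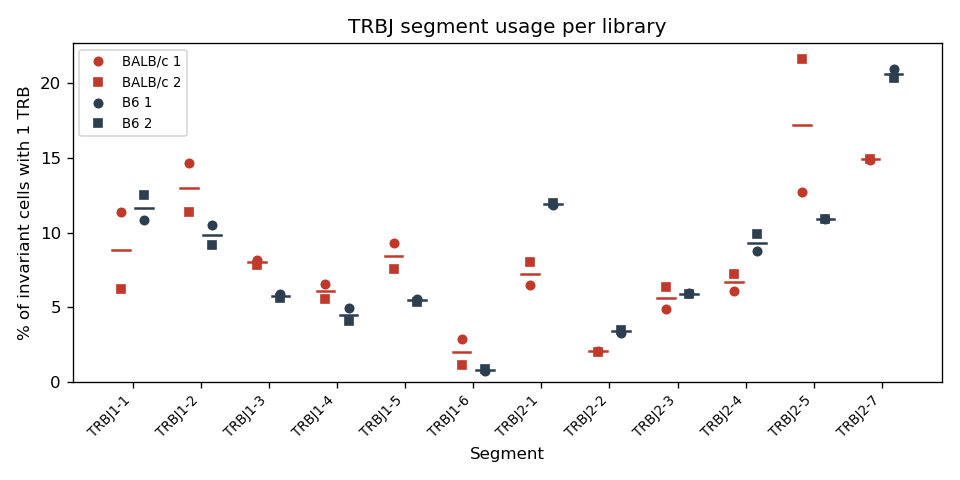
Share of invariant cells (%) that use each of 12 TRBJ segments, with 1 point per library and a bar at the mean of each strain (n = 2 libraries). TRBJ1-3 and TRBJ1-5 are higher and TRBJ2-1, TRBJ2-2 and TRBJ2-7 lower in both BALB/c libraries, and the high TRBJ2-5 point is BALB/c 2 at 21.7%.

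The middle of the CDR3 beta, without the 4 residues at each end, differed in a few amino acids. These counts depend on TRBV and TRBJ usage, and no alternative held TRBJ usage fixed, so they are not separate from the TRBJ difference. The CDR3 of the 83-cell clonotype of BALB/c 2, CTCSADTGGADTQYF, has aspartate in that middle. Aspartate was still called without the 2 largest clonotypes, but not with each clonotype counted once. Over its 14 alternatives with all 4 libraries it was called in 4. edgeR called 5 of 20, with aspartate higher and histidine, isoleucine, leucine and tyrosine lower in BALB/c. Aspartate made up 15.1% ± 0.926 of residues in BALB/c and 12.7% ± 0.386 in B6 (log2 0.25, SE 0.092, adjusted p = 0.0397). The other 4 each had an adjusted p of 0.0141. Tyrosine made up 3.18% ± 0.159 and 4.12% ± 0.133 (log2 -0.37), and leucine 2.62% ± 0.0808 and 3.43% ± 0.041 (log2 -0.38). Isoleucine made up 0.397% ± 0.0981 and 0.683% ± 0.0784 (log2 -0.76), and histidine 0.424% ± 0.0662 and 0.694% ± 0.0241 (log2 -0.68). All 5 differed in the same direction in both libraries of a strain. edgeR called 0 without B6 1 and 0 without B6 2, each with 3 at an unadjusted p under 0.05, while the log2 fold change of tyrosine was -0.34 and -0.40 and that of aspartate 0.28 and 0.22. Without BALB/c 1, isoleucine was not called (log2 -0.48, adjusted p = 0.208), and without BALB/c 2 histidine was not (log2 -0.54, adjusted p = 0.107). Some fold changes also shrank. With each clonotype counted once they were 0.12 for aspartate, -0.36 for histidine and -0.46 for isoleucine, and in all cells with 1 TRB -0.39 for histidine, -0.27 for isoleucine and -0.17 for leucine. In TRBV13-2 cells alone histidine was at -0.13, with adjusted p = 0.748, the highest over its alternatives with all 4 libraries (lowest 0.00344). edgeR called 0 in TRBV13-2 cells alone, with 5 at an unadjusted p under 0.05. DESeq2, whose size factors raised the median of all residues by 0.14, called 0 with 4 at an unadjusted p under 0.05. Limma on log2 odds called 4, of which only histidine and isoleucine were among the 5. The mean CDR3 beta length was 14.1 ± 0.13 residues in BALB/c and 14.3 ± 0.0625 in B6, a difference of -0.16 residues (exact permutation p = 0.333). Without BALB/c 1 the length difference was -0.0686 residues, and without BALB/c 2 it was -0.252 residues. It was -0.342 residues in TRBV13-2 cells alone and -0.0888 residues with each clonotype counted once (exact permutation p = 0.333 for both).

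Repeated TRB clonotypes, cells with the same TRBV, TRBJ and CDR3 beta nucleotides, were more frequent in both BALB/c libraries than in both B6 libraries. With every library thinned to 896 cells, 32.4% of cells in BALB/c 1 and 27.2% in BALB/c 2 belonged to a clonotype seen more than once, against 1.84% in B6 1 and 3.21% in B6 2. The mean was 29.8% ± 3.69 in BALB/c and 2.53% ± 0.964 in B6. The difference of 27.3 points exceeded the spread between libraries, with an exact permutation p of 0.333, the smallest possible here. The same thinning left 37.9, 20.0, 0.13 and 1.26 clonotypes of at least 3 cells in BALB/c 1, BALB/c 2, B6 1 and B6 2, as means over 100 draws. Without thinning, 35.1%, 27.2%, 3.49% and 13.1% of cells were in repeated clonotypes, with means of 31.2% ± 5.57 in BALB/c and 8.30% ± 6.80 in B6. Clonotypes of at least 5 cells then numbered 23, 6, 0 and 4.

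The largest clonotypes each occurred in a single library. TRBV13-2 with TRBJ1-1 and the CDR3 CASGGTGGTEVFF was found in 92 cells of B6 2, which is 1.34% of its cells (interval 1.09 to 1.64). TRBV1 with TRBJ2-5 and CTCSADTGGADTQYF was found in 83 cells of BALB/c 2, 9.26% (7.54 to 11.3). TRBV13-2 with TRBJ1-6 and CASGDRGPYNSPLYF was found in 20 cells of BALB/c 1, 1.72% (1.12 to 2.64). The largest clonotype of B6 1 had 3 cells.

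**Figure D3:**
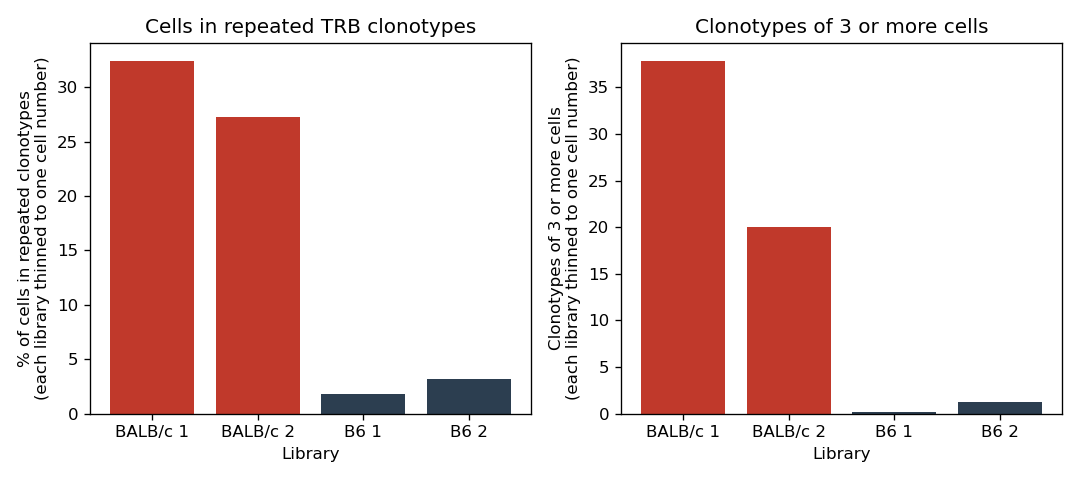
Left, share of invariant cells (%) in TRB clonotypes seen more than once. Right, number of clonotypes of at least 3 cells, with 1 bar per library in both panels, each library thinned to 896 cells and averaged over 100 draws. The BALB/c bars stand at 32.4% and 27.2% on the left, and the B6 bars at 1.84% and 3.21%.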

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

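All tests in this part were chosen after the result was seen. Among sorted cells in which only other TRA chains were found, TRAV13 with TRAJ50 stood out in BALB/c. It was in 11 cells of BALB/c 1 and 8 cells of BALB/c 2, against 1 cell of B6 1 and 2 cells of B6 2. By segment name it lay outside the planned classes. Whether it belongs to the class meant for Vα10 NKT cells was not established. It was picked for counts above the limit that a count of 0 allows, 3 cells, in both BALB/c libraries. Its contrast with B6 is therefore built in to some degree. The 19 BALB/c cells had 19 distinct TRB clonotypes, and the 17 of them with a CDR3 alpha of 13 residues, the commonest length, had 17, which argues against 1 expanded clonotype. Over all lengths they made up 5.0% of BALB/c cells with another TRA (95% Wilson interval 3.22 to 7.68) against 0.606% in B6 (0.206 to 1.77). With 13 residues, a length taken from these cells, the shares were 4.47% (2.81 to 7.05) and 0.202% (0.0357 to 1.14). The share among cells with another TRA was thus higher in BALB/c. Because the pairing was picked for its BALB/c counts, these intervals cannot decide whether a mere excess of such cells made the pattern. Pooled intervals also leave out the variation between libraries, and the intervals of BALB/c 2 (1.76 to 7.26) and B6 1 (0 to 2.40) with 13 residues overlap. Over all TRAV names the shares were 5.26% (3.43 to 7.99) and 0.606% (0.206 to 1.77) with that length and CDR3 end, and 9.21% (6.70 to 12.5) and 2.42% (1.39 to 4.19) for all TRAJ50 chains. These shares argue against the same chain being named otherwise in B6, but they contain the picked BALB/c cells, so the evidence is weak. A strain difference in a second tetramer-binding receptor may account for the pattern and stays open, untested, as do differences between animals; 16 of the 17 cells with 13 residues used Vβ8 and 16 were named TRAV13N-3.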

How the results depend on the processing

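The alternatives without the 2 largest clonotypes, with the joint segment name kept apart and with crossed pairing as a block were chosen after the data were seen. The lone library of a strain was assumed to vary like the other strain. Over single libraries left out, counts past the threshold ranged from 0 to 1 for TRBV, 0 to 9 for TRBJ, 0 to 5 for residues and 15 to 18 for invariant against other cells, and the Vβ8 difference from -2.80 to 4.13 points. TRBV gave 1 call, TRBV13-2, with the joint name kept apart. That split moves cells between names by construction. TRBJ gave 3 calls with the top TRB chain of every invariant cell and 9 without the 2 largest clonotypes. Residues gave 3 with TMM, 3 with each clonotype once (leucine and tyrosine of the main calls, and glutamate) and 2 with edgeR's abundance trend. They gave 0 with the top TRB chain, with all cells with 1 TRB, with DESeq2 and in TRBV13-2 cells alone, where 5, 4, 4 and 5 had an unadjusted p under 0.05. With each clonotype once, 2 lists passed, 1 of them the negative control. The Vβ8 difference was 3.02 points with each clonotype once and turned to -0.504 points with at least 3 UMIs and -4.64 points in all cells with 1 TRB. The difference in another TRA turned to 7.07 points with at least 10 TRA UMIs, and that in the commonest CDR3 alpha to 6.68 points with each nucleotide sequence once. For these changes the cause was not tested.

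With the replicate number as a block, 0 TRBV, 5 TRBJ (3 of the 5 called without it), 4 residues and 0 lists passed. With the numbers crossed, 0 TRBV, 1 TRBJ (TRBJ1-6, with 0 of the 5 kept) and 1 residue (isoleucine, also called without the block) passed. Libraries of the same number correlated across items with r = 0.02 (TRBV), -0.29 (TRBJ) and -0.29 (residues). These values gave no sign of pairing by number, but so few dependent items cannot exclude it. No paired analysis was possible for the single values, because the libraries share only a number. The difference in repeated clonotypes ranged from 22.9 to 27.3 points over its alternatives and from 24.7 to 29.9 points over libraries left out. Among segments not called, the sign turned in 21 of 204 TRBV values, 2 of 133 TRBJ values and 1 of 10 TRBV values between invariant and other cells, and among called items in 0. Over libraries left out, log2 fold changes ranged from -0.10 to 0.81 for TRBV1, -0.13 to 0.10 for TRBV13-2, -0.30 to 0.14 for TRBV13-3, -0.32 to 0.58 for TRBV19, -0.18 to 0.80 for TRBV31, -0.26 to 0.12 for TRBJ2-3, and -0.070 to 0.075 for TRBV13-3 between invariant and other cells. With each clonotype once they were -0.076 for TRBV1, -0.020 for TRBV13-2, 0.15 for TRBV13-3 and 0.14 for TRBV19. In all cells with 1 TRB they were 0.38 for TRBV10, -0.15 for TRBV13-2, 0.90 for TRBV19, 0.068 for TRBV5 and 0.0061 for TRBJ2-3. DESeq2 gave 0.0048 for TRBV13-3 and 0.033 for TRBV19. TRBV1 was -0.16 without the 2 largest clonotypes, and TRBV13-2 was -0.0067 with at least 3 UMIs. TRBV19 was 0.058 with the replicate block, 0.45 with the top TRB chain and 0.20 with limma on log2 odds. For these too the cause was not tested. Called TRBJ segments kept their call in 68 of 95 values, called residues in 41 of 90, and TRBV segments between invariant and other cells in 173 of 178. Barcodes shared between libraries with the same TRB numbered 0, so leaving them out tested nothing. For TRBJ, the other filters on low counts left all segments in and tested nothing either. The values above include these settings, so they overstate how often TRBJ and residue calls were kept. By depth, a count of 0 allows up to 0.335% of invariant cells in BALB/c 2 and 0.0436% in B6 2.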

Other observations

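The tests in this part of the repeated clonotypes, the TRBJ segments, the superantigen list and TRBJ1-6 were chosen after the results were seen. TRBJ1-6 had positive log2 fold changes in 3 populations of cells from the same 4 libraries, 1.33 (SE 0.45) in invariant cells, 1.39 (SE 0.61, edgeR adjusted p = 0.382) in cells with another TRA and 2.31 (SE 0.84, edgeR adjusted p = 0.136) in cells with only a TRB; none passed the threshold. In cells with another TRA the value rests on BALB/c 2, with 6.18% against 1.91% in BALB/c 1 and 1.45% and 1.60% in B6 1 and 2. The populations are not independent, since cells with only a TRB can carry a clonotype of an invariant cell. In BALB/c 1, 20 of the 33 invariant TRBJ1-6 cells were 1 clonotype, and with each clonotype counted once the value in invariant cells was 0.56 (edgeR adjusted p = 0.185), and without BALB/c 1 it was 0.43 (edgeR adjusted p = 0.430). The BALB/c libraries also shared more clonotypes when equal numbers were drawn. With 709 amino acid clonotypes drawn from each, BALB/c 1 and 2 had 19.0 in common as a mean over draws, the B6 libraries 4.36 and pairs across strains 5.41 to 8.80. By nucleotides, with 713 drawn, the means were 9.05, 0.91 and 1.29 to 4.0. Without drawing, 23 amino acid clonotypes were shared by the BALB/c pair, 89 by the B6 pair and 17 to 67 across strains. The draw took all or nearly all clonotypes of BALB/c 2 but a small part of those of B6 2 (713 and 6363 by nucleotides). Strain and library size cannot be told apart here, and with only 1 pair per strain this has no test.

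In BALB/c 1, a TRBV29 with TRBJ1-2 clonotype (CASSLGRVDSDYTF) counted 14 cells, all with a TRA chain of CDR3 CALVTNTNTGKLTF beside or in place of the invariant chain. The invariant chain was found in 9 and not found in 5. Cells with only a TRB carried a clonotype of an invariant cell in 16.3% of BALB/c 1, 12.2% of BALB/c 2, 7.42% of B6 1 and 12.4% of B6 2, so part of the cells without a found invariant chain share a TRB with invariant cells.

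The repeated clonotypes of BALB/c were weighed against technical explanations. Averaged over repeated clonotypes, 96.1% of cell pairs within a clonotype had the same CDR3 alpha nucleotides in BALB/c 1, the lower BALB/c library. Between clonotypes the share was 26.1% in BALB/c 1 and 22.1% in BALB/c 2. These values argue against independent cells with the same rearrangement. In B6 1 and B6 2 the averages within a clonotype were 87.4% and 85.4%. Free TCR RNA is argued against by the TRB UMIs, whose median in repeated over unrepeated clonotypes had a ratio of 0.944 in BALB/c 1 and 1.46 in BALB/c 2. The number of animals or starting cells behind each library cannot be told apart from strain, because the labels do not give it; the exact permutation p of 0.333 is the smallest this design allows and does not bear on it. A strain difference in clonal expansion may also account for the pattern and was not tested apart from it.

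For the TRBJ difference, a few large clonotypes are argued against, since 4 of the 5 called segments kept call and direction with each clonotype counted once. A different TRBV mix is argued against in part, since 6 segments were called in TRBV13-2 cells alone, all in the direction of all cells, but only 2 of the 5; all 12 segments kept their direction there, and those that lost the call had log2 0.38 (TRBJ1-3), -0.72 (TRBJ2-2) and -0.38 (TRBJ2-7) against 0.49, -0.74 and -0.47 in all cells. The criterion for that test was changed from the kept calls to the number called after the 2 of 5 had been seen, so it is weak evidence. TRBJ usage set before selection may contribute and stays open. All cells were sorted as CD3+ and tetramer-binding, so none shows usage before selection and the correlation cannot decide. Across the 12 segments, which are not independent replicates, log2 fold changes in invariant cells and cells with another TRA had r = 0.528 (permutation p = 0.0831) and rho = 0.301 (permutation p = 0.345). TRBJ1-6 was the largest in both (1.33 and 1.39). Of the 5 called segments, TRBJ2-1 (-0.23) and TRBJ2-2 (-0.36) kept their direction in cells with another TRA. TRBJ1-3 (-0.63), TRBJ1-5 (-0.02) and TRBJ2-7 (0.08) did not.

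Deletion by endogenous superantigens was a hypothesis for cells with another TRA. The superantigen list covered 10.8% and 14.6% of them in BALB/c 1 and 2 and 23.2% and 20.2% in B6 1 and 2. Of its 5 members only TRBV12-1, with 1.91% and 2.81% against 7.25% and 7.05% (edgeR adjusted p = 0.157), was lower in both BALB/c libraries than in both B6 libraries, and in cells with only a TRB the list covered means of 9.16% ± 3.33 in BALB/c and 8.34% ± 3.69 in B6, a gap within the spread between libraries. By fry its p was 0.0769 and its adjusted p over 3 lists 0.193, so the hypothesis may hold but the test did not pass. The Mls-1 list covered 17.8%, 14.0%, 13.0% and 12.2%.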
